A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

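Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in Saccharomyces cerevisiae BY4741, a common haploid laboratory strain of mating type a. The strains carried a synthetic copy of the human HPRT1 locus or HPRT1R, its reversed sequence. Each construct was held either on a yeast artificial chromosome (YAC) or integrated on chromosome XI, which gave 4 groups of 3 libraries. Per the labels' protocols, cells were grown at 30 °C for 6 h after dilution, harvested near an OD of 0.6 and tagmented for 30 min at 37 °C, and libraries were amplified with 11 PCR cycles. Per the same protocols, YAC strains grew in SC-Leu and integrated strains in YPD, so medium and format differ together in all comparisons of formats.

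The deposited values were MACS2 peak lists, 1 per library, with no list pooled over libraries. Per the submitters' processing notes, the tools included bcl2fastq 2.20, Bowtie2 2.2.9, SAMtools 1.9, deepTools 3.5.0 and MACS2 2.1.0, and the build was sacCer3. The peak-calling options, the handling of read ends and of multi-mapping reads, and any filter on duplicates are not given in the sources used here. Each deposited row held a position, a score, a fold enrichment at the summit as a ratio to the local background, and the -log10 of a p-value and of a q-value, all as the authors' peak caller gave them. The deposited score was not used. Fold enrichment and the deposited -log10 values served only to describe, rank or filter peaks within a list, and for the recovered pileups described here. Read totals per library are unknown from these lists, so no interval on read counts is given.

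The peaks of a list never overlapped or touched (0 such pairs). Peak density was the number of peaks per kb, and covered share the percentage of bases in peaks. Both were computed for the construct contig and for the 16 nuclear chromosomes of the same library, and the log2 ratio of construct to chromosomes was the unit of the tests. A construct's length was the span from its first to its last peak over its 6 libraries, 113.862 kb for HPRT1 and 113.892 kb for HPRT1R, because the contig sequence was not used here. Chromosome lengths were taken as the farther of the last gene end and the last peak end, 12070.2 kb in all. The contig names carry that of a vector. Past 100 kb, 3 of 5 HPRT1 regions had both edges within 50 bp of an HPRT1R region, against 0 of 52 before 100 kb, and that part was left out in an added alternative. The main values used the full span for all libraries, although no integrated library held a peak past 100 kb. Density and covered share of integrated constructs are therefore lower than before 100 kb alone.

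Gene positions came from the RefSeq gene table of the R64 assembly, which is the sequence of sacCer3, with strand taken from the systematic names. A promoter ran from 500 bp upstream to 100 bp downstream of the annotated gene start, and a gene was counted as present in a library when a summit lay in it. In all, 6002 protein-coding genes had such a promoter. As a check of positions, 15.6% of promoters held a summit, against 4.88% and 5.16% after shifting the promoters by 3 kb in each direction. Of 430 members of the 21 gene lists, 428 were matched by symbol.

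Construct against chromosomes was tested with an exact two-sided sign-flip permutation test over the 6 libraries of a construct, whose smallest p is 0.0312. HPRT1R against HPRT1 and YAC against integrated were tested with exact two-sided permutation tests within the other factor, whose smallest p is 0.005. With 3 libraries against 3, no p can go below 0.1. Promoter presence was tested per gene with Fisher's exact test and Benjamini-Hochberg adjustment, and gene lists with the exact permutation test on the list's share minus the share of all genes, adjusted over the lists. Consensus regions for mirrored positions had a peak in at least 2 of 3 libraries of each group. Mirrored positions were tested by the highest overlap over all shifts, in steps of 50 bp, against 1000 random arrangements of the same regions. The labels do not say whether replicates were grown as separate strain isolates, so p-values measure the spread between these libraries.

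Under MACS2's Poisson model with a pseudocount of 1, the fold enrichment and the p-value of a summit fix its whole read pileup and its local background. A whole pileup that matched the deposited -log10 p within 0.01 was found for 99.9% of the 13746 peaks, and the other 13 were left out of those values. The lowest background at a nuclear peak, taken as the library-wide level, was 4.97 to 6.93 reads. To weigh local depth, summit pileups were thinned by binomial draws, 200 per library. Each thinning used a single ratio, taken from medians of the local background, so it matched the typical depth of a construct and not the depth at each position.

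The genes and regions named in the text followed a rule written before the data were examined. It took construct regions with a peak in all 6 libraries, the 8 highest by mean within-library percentile of fold enrichment, and those present in 3 of 3 libraries of a format and 0 of 3 of the other. It took genes present in all 6 libraries of a side and none of the other, filled up from 6 against 1 and 5 against 0, up to 4 members per gene list, the markers deleted in BY4741, and genes near format-specific regions of chromosome XI. The construct regions written out in full were picked from that set after their values were seen. Alternatives fixed before the data were examined were a -log10 q of at least 10, equal numbers of peaks per library, each replicate left out in turn, other promoter and genome definitions, and replicate numbers as pairs. Alternatives added after seeing the data were a fold enrichment of at least 3, the construct before 100 kb alone, mirrored positions by format, lists against all genes, the filters within each format, and filtered density ratios with each library left out.

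The steps were tested on simulated data. The pileup was returned exactly for 100% of 2000 simulated summits. A log2 density difference of 1 between YAC and integrated libraries came back as 1.01, and 3.5% of draws without a difference passed the threshold. For promoter peaks of YAC against integrated libraries, simulated over 6002 genes, 100% of 200 genes changed from all to none were called. At presence of 90% against 10%, 0% were called. With 2040 genes tested, at least 89 genes at 6 libraries against 0 are needed before any can be called, so this test could not detect a small set of changed promoters. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.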

Results

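Peak lists from 12 ATAC-seq libraries of yeast were compared, 3 for each combination of construct (HPRT1 or HPRT1R) and format (YAC or integrated on chromosome XI). HPRT1 encodes a human purine salvage enzyme, and HPRT1R is the same synthetic locus with its sequence reversed. The lists held 982 to 1343 peaks per library. Of these, 913 to 1303 lay on the nuclear chromosomes and 19 to 57 on the construct.

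The first comparison asked whether the synthetic sequences were accessible in yeast and how they compared with the host genome. Both constructs carried more peaks per kb than the yeast chromosomes in all 12 libraries. HPRT1 had 0.451 ± 0.0221 peaks per kb on the YAC and 0.190 ± 0.0221 when integrated (mean ± SD, n = 3 each), against 0.0833 ± 0.0016 and 0.0930 ± 0.0133 on the chromosomes of the same libraries. HPRT1R had 0.480 ± 0.0221 on the YAC and 0.296 ± 0.0355 when integrated, against 0.0818 ± 0.00552 and 0.102 ± 0.00481. The construct to chromosome density ratio was 3.33 for HPRT1 (log2 1.74) and 4.11 for HPRT1R (log2 2.04), each with p = 0.0312 in the exact sign-flip permutation test over 6 libraries, the smallest p it allows.

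Peaks covered 25.3% ± 1.66 of HPRT1 on the YAC and 6.94% ± 1.15 when integrated, and 25.1% ± 0.921 and 9.62% ± 0.423 of HPRT1R (n = 3 each). On the chromosomes, 2.63% to 4.17% of bases lay in peaks. The covered share differed from that of the chromosomes by log2 1.99 for HPRT1 and 2.22 for HPRT1R, each with p = 0.0312 in the same exact test. Construct peaks had a lower fold enrichment over local background than chromosomal ones, by the authors' values. Their median lay at percentile 18.001 ± 9.47 of a library's own peaks for HPRT1 and 18.8 ± 7.73 for HPRT1R (n = 6 each, p = 0.0312 against 50 in the exact sign-flip permutation test). By format, HPRT1 libraries lay at 6.65 to 12.7 on the YAC and 23.1 to 28.4 when integrated. HPRT1R libraries lay at 6.89 to 21.7 on the YAC and 18.9 to 26.7 when integrated. Among peaks with a fold enrichment of at least 3, the difference from 50 was -8.46 points for HPRT1 (p = 0.406) and -15.3 for HPRT1R (p = 0.0312, exact sign-flip permutation tests).

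The size of the excess depended on how peaks were filtered in both formats, and its direction in integrated strains. At a fold enrichment of at least 3, the density ratio summed over 3 libraries was 1.39 for integrated HPRT1 and 1.91 for integrated HPRT1R, and 2.42 and 2.65 on the YAC. At a -log10 q of at least 10, it was 0.398 for integrated HPRT1, with 0 to 2 construct peaks per library, and 1.14 for integrated HPRT1R, with 0 to 7. Leaving out each library in turn gave 0.170 to 0.558 for HPRT1 and 0.424 to 1.59 for HPRT1R. On the YAC the ratio at that -log10 q was 21.7 for HPRT1 and 33.4 for HPRT1R. Median summit pileups on those YACs were 99.3 and 136 reads, against 20 to 26 at nuclear peaks. At the same fold a deeper summit has a higher -log10 q, and YAC constructs were not thinned to the library-wide background. The YAC excess over the chromosomes was therefore not separated from depth.

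**Figure D1:**
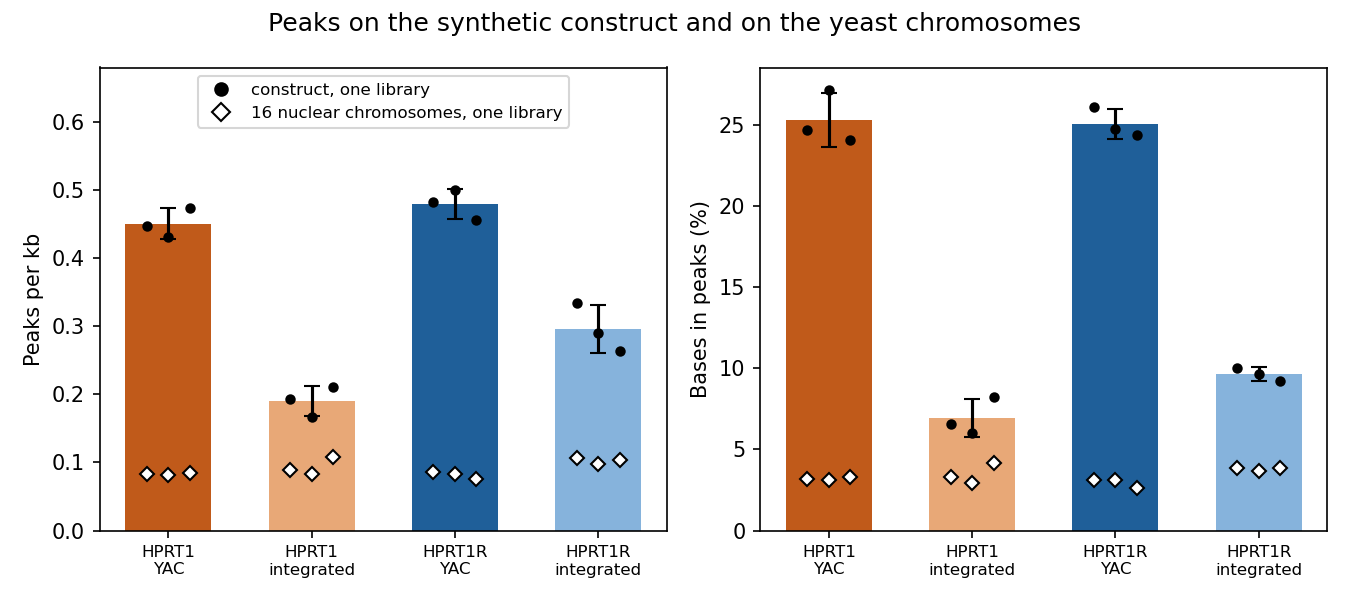
Peaks per kb (left) and percentage of bases in peaks (right) in the 4 groups. Bars and error bars are the mean and SD of the construct over 3 libraries, filled points are the construct in each library and open diamonds the 16 nuclear chromosomes of the same library. Every filled point lies above its diamond, and YAC libraries lie above integrated ones.

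Along HPRT1, 57 regions held a peak in at least 1 of 6 libraries, and 12 held a peak in all 6. The strongest by mean rank of fold enrichment was at contig positions 76605 to 77509, with a fold enrichment of 4.67 ± 0.277 on the YAC and 3.89 ± 0.284 when integrated (n = 3 each). The next were at 91714 to 93170 (4.72 ± 0.529 and 3.76 ± 0.312), 4231 to 5149 (4.18 ± 0.677 and 3.95 ± 0.358) and 69867 to 70677 (4.64 ± 0.631 and 3.58 ± 0.279). The regions at 43362 to 44710, 30241 to 31942, 25187 to 26123 and 68031 to 69015 completed the 8 strongest. On HPRT1R, 22 of 61 regions held a peak in all 6 libraries. The strongest was at the contig start, 33 to 1672, with a fold enrichment of 7.12 ± 0.531 on the YAC and 5.45 ± 1.02 when integrated. It was followed by 50019 to 50582 (3.99 ± 0.421 and 4.01 ± 0.697), 98014 to 98504 (3.31 ± 0.323 and 4.68 ± 0.164) and 57741 to 58336 (3.82 ± 0.297 and 3.71 ± 0.391). The regions at 31882 to 32877, 56775 to 57366, 93170 to 94024 and 96465 to 96899 completed the 8 strongest. Positions are those of the synthetic contigs, whose gene structure was not analysed here.

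The constructs were also set against stretches of the yeast genome. Among 1033 chromosomal windows of the construct's length, none held as many peaks as the construct in any of the 12 libraries. The fullest window of a library held 18 to 23 peaks. By covered share, the YAC constructs lay above all windows, and the integrated constructs lay at percentiles 98.94 to 99.03. At a -log10 q of at least 10, integrated HPRT1 fell to percentiles 0, 55.2 and 2.03 by number of peaks, and integrated HPRT1R to 30.6, 97.2 and 0.

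The silent mating-type loci on chromosome III, HML (11386 to 14809) and HMR (292179 to 295321, both with 1 kb flanks), held no peak in any of the 12 libraries. They share sequence with the MAT locus, and the handling of reads that match several places is not given in the sources used here, so this count does not show closed chromatin. The 10 kb next to chromosome ends had 0.165 ± 0.0118 and 0.200 ± 0.00313 peaks per kb in HPRT1R YAC and integrated libraries, and 0.163 ± 0.00625 and 0.197 ± 0.0108 in HPRT1 libraries (n = 3 each). These values lay above the group means for the whole chromosomes, 0.0818 to 0.102. The excess lay mainly in the last 1 kb, with 0.883 ± 0.0694 peaks per kb (n = 12). From 1 to 10 kb the density was 0.103 ± 0.0159 (n = 12), close to that of the chromosomes. The subtelomeric density was below that of HPRT1R by log2 -1.05 (p = 0.0312, exact sign-flip permutation test, n = 6). For HPRT1 it was -0.71 (p = 0.156, exact sign-flip permutation test), and in integrated HPRT1 libraries alone 0.05 ± 0.12 (n = 3). With 20 kb at chromosome ends, HPRT1 gave -1.47 (p = 0.0312, exact sign-flip permutation test). Over the 4 alternative settings with a value, HPRT1 ranged from -1.47 to 0.409, so its direction depended on the setting. With a fold enrichment of at least 3, the difference for HPRT1R was -0.05 (p = 0.75, exact sign-flip permutation test).

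The second comparison set the reversed against the original sequence. HPRT1R had more peaks relative to the chromosomes than HPRT1, by log2 0.30 or 1.23-fold (p = 0.005, exact permutation test within formats, the smallest p it allows). In integrated strains the difference was 0.49, from 1.04 ± 0.08 to 1.52 ± 0.16, and on the YAC it was 0.12, from 2.44 ± 0.04 to 2.55 ± 0.06 (n = 3 each). Each had p = 0.1, the smallest that an exact permutation test of 3 against 3 gives. The difference was larger by 0.37 in integrated strains than on the YAC (p = 0.14, exact permutation test of construct labels within formats). That test assumes no construct effect in either format, so it cannot decide whether the effect varied with the format. The covered share differed by log2 0.22 (p = 0.02, exact permutation test), with 0.34 in integrated strains (p = 0.1) and 0.10 on the YAC (p = 0.4, exact permutation tests). With a fold enrichment of at least 3, the density difference was 0.28 (p = 0.16) and the covered-share difference 0.15 (p = 0.27, exact permutation tests). The density difference at that fold was 0.48 in integrated strains (p = 0.1) and 0.07 on the YAC (p = 0.8, exact permutation tests), where HPRT1R libraries ranged from 0.78 to 1.77. Local background at construct peaks was also higher on HPRT1R than on HPRT1, by 1.32-fold (p = 0.005, exact permutation test within formats). It was 1.43-fold on the YAC and 1.22-fold when integrated (each p = 0.1, exact permutation tests). This measure was chosen after seeing the data, and depth was weighed for this comparison only in integrated strains.

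Peak positions on the 2 constructs were mirror images more often than randomly placed regions. With HPRT1R coordinates reversed, 33.4% of its consensus peak bases before 100 kb fell on HPRT1 consensus peaks at the best alignment, against a median of 17.96% for 1000 random arrangements (p = 0.002, permutation test, the smallest it can give). At that alignment a position on HPRT1 and its counterpart on HPRT1R added up to 100751. YAC libraries alone gave 45.4% (random median 31.4%) at the same alignment, with p = 0.002 in the permutation test. Integrated libraries alone have nearly the same consensus regions as both formats together, so their 33.4% is not a separate result. Without reversal, the best overlap was 24.5% (p = 0.024), in the nearly identical regions of integrated libraries alone 24.2% (p = 0.028), and in YAC libraries alone 34.4% (p = 0.13, permutation tests). With consensus regions limited to those in all 6 libraries, 19.5% of bases overlapped after reversal (p = 0.162) and 13.9% without it (p = 0.326, permutation tests).

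**Figure D2:**
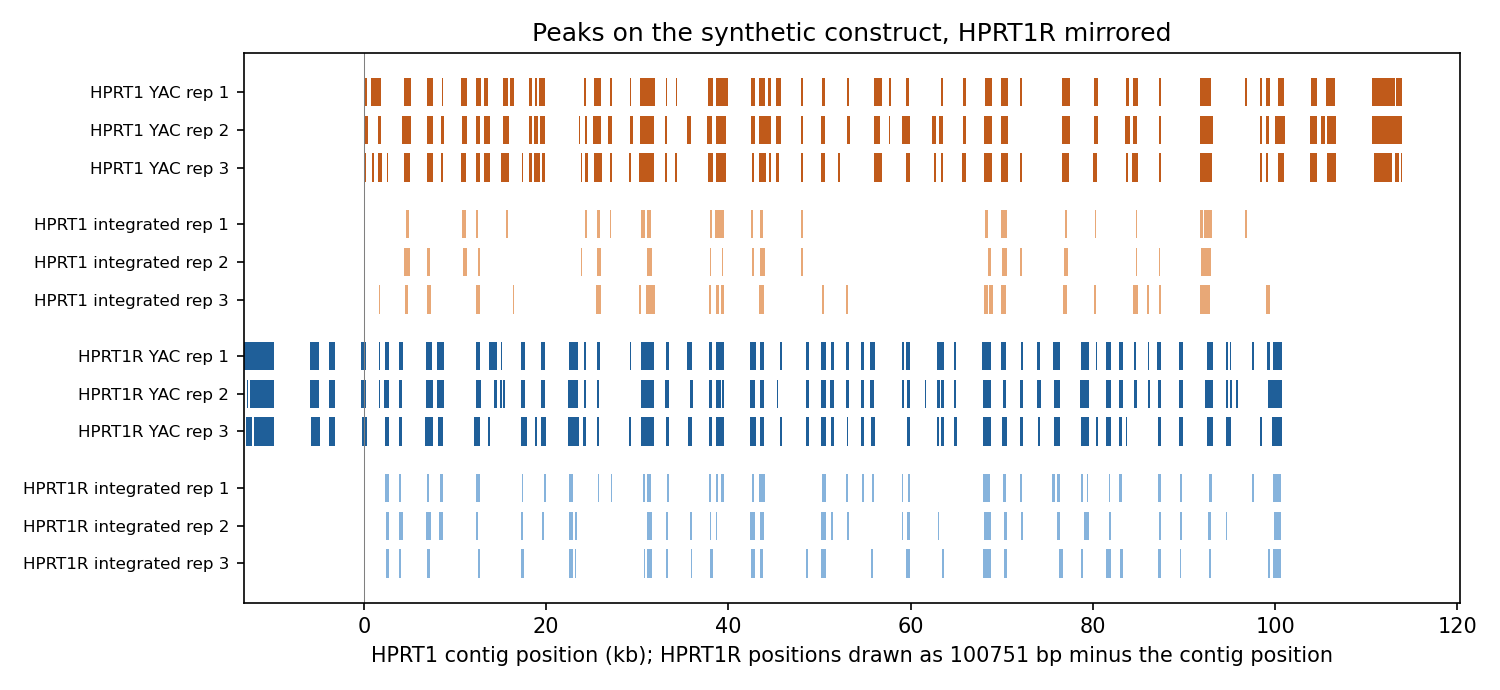
Peaks along the synthetic construct, with 1 row per library and the contig position in kb on the horizontal axis. HPRT1R positions are drawn as 100751 minus the contig position, so mirrored regions line up vertically, as at the HPRT1 regions 30241 to 31942 and 68031 to 69015.

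The third comparison set the episomal against the chromosomal format. YAC libraries had more construct peaks relative to the chromosomes than integrated libraries, by log2 1.21 or 2.32-fold, and a larger covered share, by log2 1.87 or 3.65-fold (each p = 0.005, exact permutation test within constructs). The density difference was 1.40 for HPRT1 and 1.03 for HPRT1R. On HPRT1, 18 regions had a peak in 3 of 3 YAC and 0 of 3 integrated libraries, and on HPRT1R 8 did. No region on either construct had the opposite pattern. The HPRT1 region at 55973 to 56856 was among the stronger ones on the YAC, with a fold enrichment of 4.45 ± 0.744 (n = 3), and held no peak in the 3 integrated libraries. It lay in a stretch of 14.9 kb, 53129 to 68030, that held no peak in any integrated HPRT1 library. Other HPRT1 regions of this kind were at 18131 to 18438 (2.62 ± 0.202), 45212 to 45825 (2.66 ± 0.295) and 59053 to 59901 (2.59 ± 0.243). On HPRT1R those before 100 kb were at 26465 to 26871, 35673 to 36000, 76313 to 76686 and 86173 to 87075.

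Past 100 kb, 4 regions on each construct had a peak in all 3 YAC and no integrated library. The largest, at 110609 to 113926 on HPRT1 and 110585 to 113924 on HPRT1R, had fold enrichments of 4.54 ± 0.643 and 4.72 ± 0.265 on the YAC (n = 3 each). Before 100 kb alone the density difference between formats was log2 1.07 (p = 0.005, exact permutation test). Over the whole contig, with a fold enrichment of at least 3, it was 0.61 (p = 0.02, exact permutation test).

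Local read background on the construct also differed between formats. The median background at construct peaks was 6.46 ± 0.797 times the library-wide level on the HPRT1 YAC and 1.27 ± 0.0486 times when integrated, and 9.23 ± 1.02 and 1.55 ± 0.0031 times for HPRT1R (n = 3 each). The YAC to integrated ratio was 5.47-fold (log2 2.45, p = 0.005, exact permutation test, a measure chosen after seeing the data). The median summit pileup was 99.3 ± 12.9 and 136 ± 12.9 reads on the HPRT1 and HPRT1R YACs, and 25.5 ± 1.32 and 28.3 ± 1.53 when integrated, against 20 to 26 reads at nuclear peaks.

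**Figure D3:**
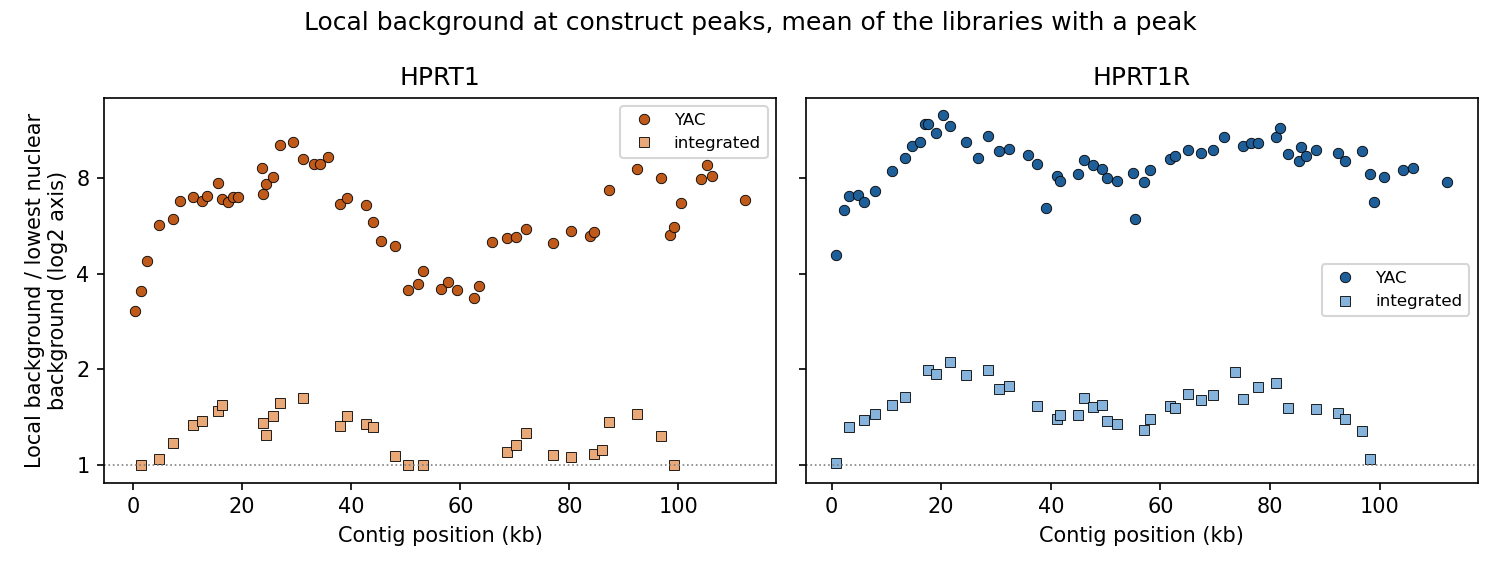
Local background at construct regions, divided by the lowest background at a nuclear peak of the same library and averaged over the libraries with a peak, against contig position in kb. The vertical axis is on a log2 scale, circles are YAC and squares integrated libraries, and the dotted line marks 1. YAC circles range from 3.04 to 10.3 on HPRT1 and from 4.56 to 12.6 on HPRT1R, above the integrated squares throughout.

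On the yeast chromosomes, promoter peaks were compared between formats, which also differ in medium. Of 6002 genes, 182 had a promoter peak in all 12 libraries and 3780 in none. YAC libraries had a promoter peak at 14.3% ± 0.688 of genes and integrated libraries at 17.0% ± 2.02 (n = 6 each). None of the 2040 genes tested passed an adjusted p of 0.05 in Fisher's exact test, and 3 genes more often present in YAC and 8 more often present in integrated libraries had an unadjusted p under 0.05. In a design of this size no fewer than 89 genes at 6 against 0 would have been called, so the count of 0 does not show that promoters were alike.

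SOM1 (chromosome V, 42400 to 42624), a subunit of the mitochondrial inner membrane peptidase, had a promoter peak in 6 YAC and 0 integrated libraries, and LSB5 (chromosome III, 61658 to 62722) in 0 and 6 (unadjusted p = 0.00216 each, Fisher's exact test). GRX1 (III, 60841 to 61173), a glutaredoxin that shares its upstream region with LSB5, had 0 and 5. SUP35 (IV, 808324 to 810381), a translation termination factor, had 6 and 1, and BUD22 (XIII, 298868 to 300427) had 5 and 0. CHA1 (III, 15798 to 16880), which encodes a serine deaminase, and its divergent neighbour VAC17 (III, 17290 to 18561), needed for vacuole inheritance, each had 0 and 5. So did TOS7 (XV, 288898 to 290553), the pyridoxine transporter gene TPN1 (VII, 151037 to 152776) and the vacuolar zinc transporter gene ZRC1 (XIII, 754838 to 756166). GAL2 (XII, 290212 to 291936), the galactose permease gene, had 1 and 6. Their mean fold enrichment where present ranged from 2.69 for ZRC1 to 3.77 for TOS7. Each of these had an unadjusted p of 0.0152 apart from SOM1 and LSB5, and an adjusted p of 1.

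None of the 21 gene lists passed an adjusted p of 0.05 between formats (exact permutation test, smallest adjusted p 0.0525). This smallest value was shared by 8 lists, 5 higher in YAC and 3 higher in integrated libraries. The smallest unadjusted p of this test is 0.005, and a single list at that limit cannot pass over 21 lists. The purine and the thiamine and vitamin B6 lists both lay at it. The lack of passing lists therefore does not show that lists were alike, and under 6 alternative settings 0 to 12 lists passed. Purine biosynthesis genes had a promoter peak at 15.3% ± 3.40 in YAC and 33.3% ± 7.45 in integrated libraries (n = 6 each), a difference of -15.3 points relative to all genes (p = 0.005, adjusted p = 0.0525, exact permutation test). Of its 12 members, 6 were present in more integrated libraries and 0 in more YAC libraries, among them ADE8 (3 YAC and 6 integrated libraries), SHM2 (2 and 5), ADE12 (2 and 4) and ADE3 (3 and 5). With the promoter limited to 300 bp upstream, that difference was -2.39 points (adjusted p = 0.641), and at a -log10 q of at least 10 it was -2.32 (adjusted p = 0.531, exact permutation tests). Ribosomal protein genes had 56.3% ± 6.82 and 65.2% ± 4.26 (-6.08 points, p = 0.03, adjusted p = 0.07, exact permutation test), with 15 of 132 members present in more YAC and 49 in more integrated libraries. Examples were RPL31B (2 and 6), RPL8B (1 and 5) and RPL22B (1 and 5). All genes also had fewer promoter peaks in YAC libraries, 14.3% against 17.0%. A loss in proportion to the share gives more points in a list with a high share. The ribosomal difference therefore does not show a change beyond that of all genes.

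Among other nutrient lists, amino acid biosynthesis genes had 29.3% ± 11.3 in YAC and 35.9% ± 4.03 in integrated libraries, with TRP3 at 5 and 1 and both ARG3 and ARO4 at 3 and 6. Methionine and sulfur assimilation had 30.6% ± 13.0 and 39.8% ± 10.2, with MET3 at 0 and 3. Amino acid permeases had 34.4% in both. The iron regulon had 28.6% ± 6.39 and 26.2% ± 7.38, with TIS11 at 1 and 5 and HMX1 at 6 and 4. The phosphate regulon had 23.3% ± 6.99 and 24.4% ± 5.44, and hexose transporters had 29.6% ± 9.07 and 31.5% ± 8.36. Ergosterol biosynthesis had 20.8% ± 7.36 and 34.2% ± 13.6, with ERG6 at 1 and 5. Respiration genes had 19.4% ± 7.76 and 29.2% ± 5.89, with ATP2 at 3 and 6. Heat shock and stress genes had 24.6% ± 2.72 and 31.6% ± 7.44, and a-cell mating genes had 15% ± 5.48 and 26.7% ± 5.16 (-8.90 points, p = 0.02, adjusted p = 0.0525, exact permutation test), with STE6 at 1 and 4. At a -log10 q of at least 10 the a-cell difference turned to 1.85 points, as for lists without any peak. Thiamine and vitamin B6 genes had 6.86% ± 2.40 and 3.92% ± 3.04, a difference of 5.70 points relative to all genes (p = 0.005, adjusted p = 0.0525, exact permutation test). Only 4 of the 17 members had a peak in any library, with SNO3 and SNZ3 at 1 and 0 and THI2 at 2 and 1. Part of the 5.70 points is the shift of all genes, which gave 2.76 points for the PAU family without any peak. Values are mean ± SD with n = 6, and none passed the adjusted threshold.

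Levels differed more between lists than between formats. Over the 12 libraries, a promoter peak was found at 75% ± 16.5 of histone genes, 66.2% ± 7.26 of glycolysis genes and 60.7% ± 7.12 of ribosomal protein genes. These lay above all genes in 12 of 12 libraries (adjusted p = 0.000854 each, sign-flip permutation test added after seeing the data, n = 12). The PAU family of cell wall genes had 0%, meiosis genes 0.758% ± 2.62, alpha-cell mating genes 2.08% ± 7.22, the subtelomeric COS family 2.78% ± 4.10 and galactose genes 8.33% ± 7.36. In lists with almost no peak, a difference between formats carries the share of all genes and not that of the list, as the PAU family shows with 2.76 points. PAU and COS genes are near copies of each other, so their low shares carry the same limit on reads that match several places. Of the markers deleted or disrupted in BY4741, URA3, MET17 and HIS3 had no promoter peak in any library, and LEU2 had a peak in 2 YAC and 0 integrated libraries. YAC strains grew in SC-Leu, so this does not show a difference at the chromosomal LEU2 locus between formats.

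**Figure D4:**
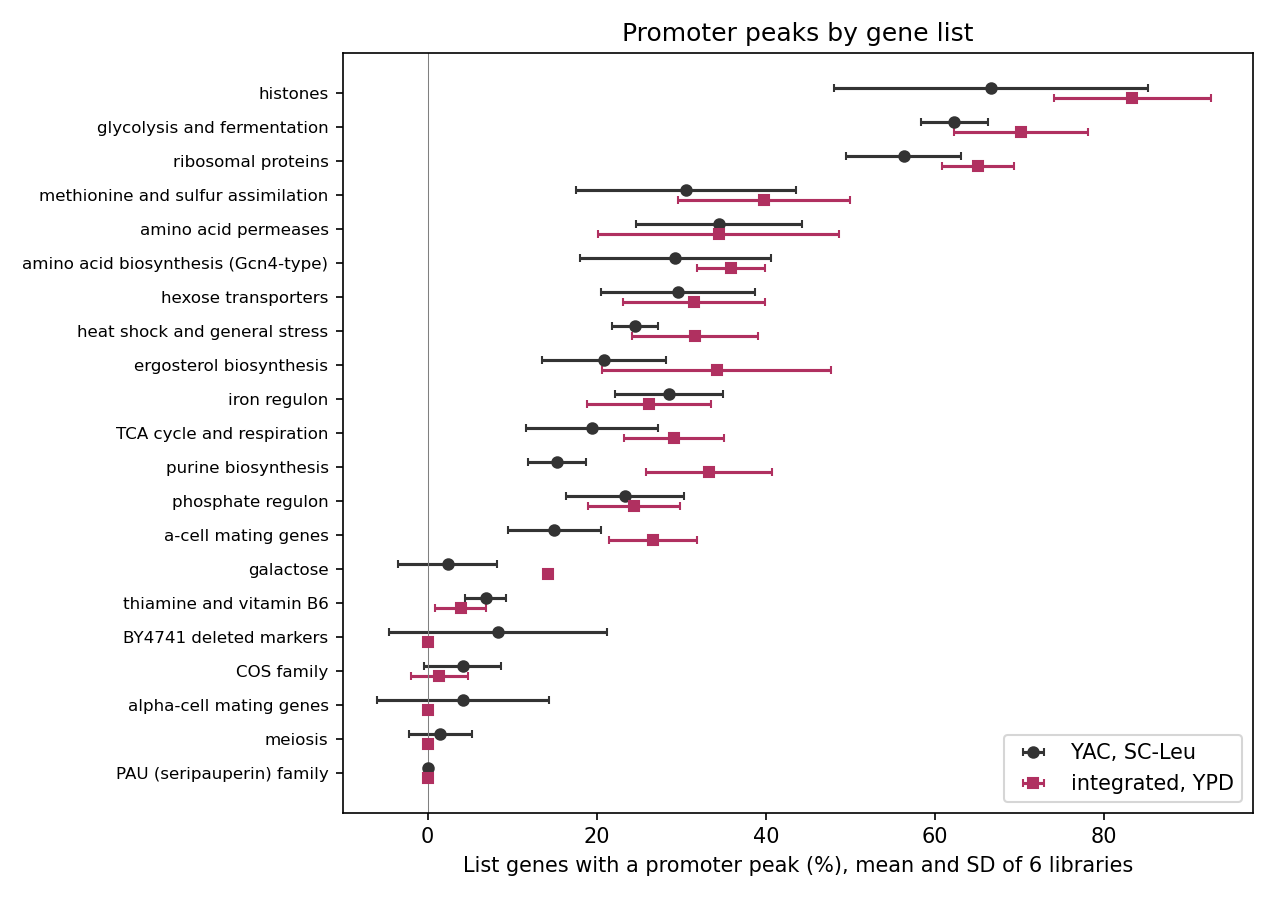
Percentage of the genes of each list with a promoter peak, for 6 YAC libraries grown in SC-Leu (circles) and 6 integrated libraries grown in YPD (squares), as mean and SD. Histone, glycolysis and ribosomal protein genes lie above 50% in both formats, and the PAU family lies at 0.

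Promoter peaks were also compared between constructs, in which the yeast genome is that of the same strain. None of 2040 genes passed an adjusted p of 0.05 in Fisher's exact test, and 1 gene had an unadjusted p under 0.05. That gene, ISA2 (chromosome XVI, 682220 to 682777), which acts in iron-sulfur cluster assembly, had a promoter peak in 5 HPRT1R and 0 HPRT1 libraries (unadjusted p = 0.0152, Fisher's exact test). None of the 21 lists passed the threshold in this comparison.

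On chromosome XI, which carries the integrated constructs, 2 regions had a peak in 3 of 3 integrated and 0 of 3 YAC libraries of HPRT1R, and none did for HPRT1. They lay at 75428 to 75885, overlapping YKT6, a SNARE gene, and at 143174 to 143515, 355 bp from PIR1, a cell wall protein gene. Over all 16 chromosomes, 40 of 1847 HPRT1R regions and 11 of 1723 HPRT1 regions had this pattern, and 3 and 6 the opposite. Integrated lists were longer, with a mean of 1285 peaks against 1060 on the YAC for HPRT1R, and 1162 against 1075 for HPRT1. Longer lists favour this pattern, and the counts were not adjusted for length. Libraries of a group shared a mean Jaccard index of 0.507 ± 0.035 of nuclear peak bases, against 0.495 ± 0.0357 between groups, a difference of 0.0124 (one-sided p = 0.00455 in the exact permutation test over 15400 assignments). Groups differed in this. HPRT1R integrated libraries shared 0.544 with each other, while HPRT1 integrated libraries shared 0.511 with each other and 0.530 with HPRT1R integrated libraries, and HPRT1R YAC libraries shared 0.470 with each other.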

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

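Mitochondrial DNA carried 17.5 peaks per library on average (SD 1.24, range 15 to 19, n = 12), in a part of the lists that the comparisons of constructs and promoters do not use. Nothing in the data predicts that number, so it is only a description. YAC libraries had 18.2 ± 0.753 and integrated libraries 16.8 ± 1.33 (n = 6 each), a difference that was not tested. With 3 libraries per group, no library was tested for standing apart from its group. HPRT1R_YAC replicate 3 shared 0.415 to 0.452 of nuclear peak bases with the other libraries (Jaccard index), while all other pairs shared 0.479 or more, and it had the shortest list, 982 peaks in all and 86 at a -log10 q of at least 10.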

How the results depend on the processing

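A fold enrichment of at least 3, the construct before 100 kb alone and the mirrored positions by format were chosen after seeing the data. Construct against chromosomes, and YAC against integrated, kept direction and threshold for density and covered share with equal numbers of peaks, without chromosome XII and chromosome ends, before 100 kb and at a fold of at least 3. Unmerged rows moved nothing, since no peaks touch. At a -log10 q of at least 10, 13 construct results have no value because 2 integrated libraries held 0 construct peaks, and the median window percentiles were 98.6 for peaks and 98.8 for covered share. That median pools 6 YAC libraries at 100 with 6 integrated libraries that ranged from 0 to 97.2 for peaks and 0 to 97.6 for covered share, so the result was lost in most integrated libraries. At a fold of at least 3, HPRT1R against HPRT1 was 0.28 (p = 0.16) for density and 0.15 (p = 0.27) for covered share, the strength of HPRT1 was -8.46 points (p = 0.406) and subtelomeres against HPRT1R were -0.0486 (p = 0.75, exact permutation tests). With 20 kb at chromosome ends, subtelomeres against HPRT1 were -1.47 (p = 0.0312, exact sign-flip permutation test), and the highest value over the alternatives was 0.409. Mirrored overlap was 19.5% for regions in all libraries, and unreversed overlap was 13.9% there and 34.4% for YAC libraries alone. The causes of these changes were not tested.

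No gene list passed between formats as planned, but 12 passed at a -log10 q of at least 10, 5 with equal numbers of peaks, 8 with promoters of 300 bp and 7 at a fold of at least 3, many of them lists with almost no peak. At a -log10 q of at least 10 the a-cell and galactose lists both reversed to 1.85 points, and with promoters of 300 bp the galactose list reversed to 1.78. Leaving out each library gave 0 to 7 passing lists, with 7 without HPRT1_YAC replicate 3 and 3 without HPRT1_integrated replicate 1 or 2. Replicate numbers did not pair the libraries (correlations of same-numbered libraries -0.0553 to 0.0208). With the replicate block, HPRT1R against HPRT1: covered share ratio stayed 0.22 with p = 0.0938 (exact sign-flip permutation test), and no other call changed.

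Leaving out each library in turn, a sign-flip over 5 libraries cannot go below 0.0625. Density against the chromosomes ranged from 1.59 to 1.89 for HPRT1 and 1.93 to 2.18 for HPRT1R, covered share from 1.77 to 2.197 and 2.02 to 2.41, strength from -34.1 to -29.7 and -32.8 to -28.8, and subtelomeres against HPRT1R from -1.18 to -0.93.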

Other observations

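Tests on tRNA genes, on the part past 100 kb, on the media, on equal numbers of peaks, on filters within each format, on the ratio of backgrounds and on other splits of the libraries were chosen after the results were seen. The limits of the thinning tests were set before any thinning, but after the peak counts they concern were known. Genes for tRNA had a summit within 200 bp at 50.3% ± 6.60 of 275 genes, against 9.10% ± 1.52 of 6002 protein-coding genes and 19.6% ± 3.10 of 76 snoRNA genes (n = 12). The share was higher for tRNA than for protein-coding genes in 12 of 12 libraries, by 41.2 points (p = 0.000488, sign-flip permutation test, the smallest it allows). In the promoter window used for the comparisons of genes, 15.6% of protein-coding genes held a summit, so the size of this gap depends on the window. The strongest region present in all 12 libraries lay on chromosome XII at 489766 to 490526, beside RRT15, with a fold enrichment of 16.7 ± 0.861. Of the 20 strongest such regions, 14 lay within 20 kb of a chromosome end, among them those at the helicase genes YRF1-8 (13.6 ± 1.92), YRF1-4 (10.1 ± 1.03) and YRF1-7 (7.27 ± 0.924), and others lay at the metallothionein genes CUP1-1 (6.30 ± 0.855) and CUP1-2 (6.18 ± 0.769). These are repeated sequences, so their fold depends on how the authors placed reads that match several copies. Peaks were dense in the last 1 kb of chromosomes (0.883 ± 0.0694 per kb) and sparse from 10 to 20 kb (0.0344 ± 0.00821, n = 12).

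More construct peaks in YAC than in integrated libraries may come from deeper local coverage of the YAC. Thinned to the integrated background, the HPRT1R YAC kept 36.7 ± 4.07 of 50 peaks before 100 kb, within the integrated range of 30 to 38, and the HPRT1 YAC kept 26.9 ± 0.984 of 46, against 19 to 24. The HPRT1 count passed the limit set before thinning, 26.5 or the highest integrated library plus 1 SD, which read at face value argues against depth as the whole cause on HPRT1. It did so by less than its own spread, and the spread was weighed only after the count was seen. The thinned HPRT1 summits were also called at a -log10 p of 2.97, the lowest of any HPRT1 integrated library. The other HPRT1 integrated libraries had stricter lowest values, 3.07 and 3.22. This favours the thinned YAC count, so depth stays open on HPRT1. The part past 100 kb was argued against as the whole cause by the log2 difference of 1.07 before it, and location cannot be told apart from medium, since 0 media were used for both formats.

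More peaks on HPRT1R than on HPRT1 in integrated strains remained after thinning HPRT1R to the HPRT1 background, at 32.9 ± 4.25 peaks before 100 kb against 19 to 24 on HPRT1. The thinned HPRT1R summits were called at the lowest -log10 p of their own libraries, 2.76 to 2.83. HPRT1 integrated libraries had stricter lowest values, 2.97 to 3.22, so this count favours HPRT1R and does not settle depth. Longer lists were argued against over both formats by the log2 difference of 0.29 with equal numbers of peaks (p = 0.005, exact permutation test within formats), and in integrated strains alone 0.45 of 0.49 remained, with p = 0.1, the smallest of an exact permutation test there. A difference in the sequences themselves may underlie it, which the design names and no value here tests. At a fold enrichment of at least 3 the difference in integrated strains was 0.48, with 0.81 to 1.06 on HPRT1R and 0.15 to 0.65 on HPRT1.

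Before 100 kb, the higher peak density of integrated constructs than of the chromosomes was lowered little by thinning to the library-wide background. It went from log2 1.47 to 1.301 ± 0.28 (above 0 in 6 of 6 libraries, p = 0.0312, exact sign-flip permutation test). Over the whole span the unthinned mean was 1.28. Local depth as the whole cause was argued against by the thinned value. The excess remained at a fold enrichment of at least 3. At a -log10 q of at least 10 it was absent for HPRT1, and for HPRT1R it rested on replicate 2, so it depends on the filter. A property of human or reversed sequence may be among several causes that were not tested.

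At the 29 HPRT1 and 38 HPRT1R regions with a peak in both formats, the ratio of YAC to integrated background had a median of 5.01 (3.53 to 6.50) and 5.81 (4.49 to 7.90), with a largest coefficient of variation of 14.6%. None of these regions lies in the HPRT1 stretch from 53129 to 68030, where the median YAC background was 3.63 times the library-wide level against 6.76 elsewhere, so the ratio there is unknown. Where the integrated background exceeded 1.1 times the library-wide level, the ratio was 4.40 to 6.50 (HPRT1) and 4.88 to 7.63 (HPRT1R). It rose along HPRT1R, with 5.03 at 7553 to 8394, 5.82 at 50019 to 50582 and 7.63 at 96465 to 96899. This rise was not tested, and a constant factor alone would not give it. For the measured HPRT1 regions a fixed number of YAC copies per integrated copy is a candidate explanation, which other constant factors would meet as well. For promoter peaks, 100 of 100 splits of the 12 libraries gave as many called genes as formats and as many as constructs, since the real count and the highest of the other splits were both 0. That outcome was fixed by the real count of 0 and says nothing about chance. At an unadjusted p under 0.05, formats gave 11 genes against at most 10 in other splits (1 of 100 gave as many, the real split), and constructs gave 1 against at most 11 (95 of 100).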
